A study of Mus musculus with 6 samples.

How the data were processed

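Expression was measured in lung tissue of CD1 mice, 3 with a sham procedure and 3 preconditioned, with an array for each mouse. RNA was extracted with Trizol and purified on columns, and 100 ng per mouse was amplified and labelled, per the labels' protocols. The deposited values are on the log2 scale and were made with RMA, which subtracts background, quantile-normalizes the arrays and summarizes the probes of a probe set, and limma was used by the submitters, per the submitters' processing notes. Versions, annotation, filters and a genome build are not given in the sources used here, so no coordinates are printed. RMA sets the arrays to a common distribution of probe values, so a change shared by most genes cannot be seen in these values. Array values have no read depth, and the number of arrays limits the precision.

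The table held 41345 probe sets. Gene symbols came from a probe annotation table, which listed 25335 of them; 16010 were not in it and are unnamed here. Of the listed ones, 1814 had several symbols and were not used under a gene name, and 23521 had 1 symbol. For a gene with several probe sets the one with the highest mean over the 6 arrays was used, which gave 22180 genes. A gene table of the mouse assembly GRCm38.p6 served only to find older symbols of list members. Ddx3y, planned for the check of sex, was not analysed here because no probe set carried its symbol alone.

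Each gene was fitted with limma (lmFit and eBayes, without trend), preconditioned minus intact, with no covariate and no filter on level, and p-values were adjusted by Benjamini-Hochberg over genes with a threshold of 0.05. Gene lists for lung cell types, the treatment and sources of unwanted variation (heart muscle, fat, thymus, blood, sampling hour, handling, sex, small RNA, olfactory receptors) were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg over the 44 lists with at least 5 measured genes. An estimated correlation and fry stood beside it. Design, gene lists, the rule for named genes and all alternatives except cyclic loess were fixed before the data were examined. Fold differences, list medians and the level trend were seen before the tests of technical explanations were written, and 2 of these tests were changed after their results. The test on resident cells was first made on the 6 lists called lower, which argued against less blood, then on all 10. There the arrays were apart too, and the need to hold without any single list was added after that was seen, as was, last, a screen of each of the 10 lists, which was dropped because it chose lists by the result tested. The clock test first left out 5 genes of its output group, and its arrays were then apart.

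Named genes were up to 15 genes per direction past the threshold, by size, then genes by lowest unadjusted p up to 10 per direction, given as values. For both, the values of the groups had to lie apart, the higher group mean had to exceed the median of all genes, and symbols of predicted genes, microRNAs, small nucleolar RNAs and receptor families were counted but not named. Up to 4 members with the largest moderated t of each described list were also named, with Ccl3 in any case, since work on ventilation preconditioning concerns it, and the sex-linked genes.

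The gene fit was tested on simulated values for the 22180 genes of this comparison. It recovered 86% of 100 genes changed by a log2 of 1 and 99% of 100 changed by a log2 of 2, with 6 unchanged genes called. A list shifted by a log2 of -0.5 was called with the estimated correlation too (adjusted p = 0.0190), and 0 of 43 unshifted lists were called at the preset correlation. Simulated genes varied independently of each other. The result therefore does not cover lists whose members vary together, as those of many lists did here. Nor does it give the share of true changes found in these data, where the number of changed genes is unknown. For example, Rnu3a at 1.88 and Il1b at -1.60 did not pass the threshold over all genes. To compare a list with genes of like level, 10000 random lists were drawn within 20 bins of mean level. Alternatives were a filter at the median level, quantile normalization again, median centring, an intensity trend with robust prior, array weights, the replicate number as a block, the mean over a gene's probe sets, all probe sets, an adjusted p under 0.1, leaving out each array in turn, and cyclic loess, which was added after the trend with level was seen. For a gene or list called under neither setting no direction was compared. R 4.3.3, limma 3.58.1, data.table (1.17.8), python 3.11.15 and matplotlib 3.10.9 were used.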

Results

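The series measured gene expression in lung tissue of 6 CD1 mice, an outbred strain, aged 10 weeks. There were 3 intact mice, which had a sham procedure, and 3 preconditioned mice, which had been mechanically ventilated at low pressure for 90 minutes 1 week before the lung was taken. From each mouse, 100 ng of total RNA was amplified, labelled with biotin and hybridised to a 1-colour whole-transcript array. The array medians lay between 5.32 and 5.40 on the log2 scale, and the correlation between arrays, taken across genes, lay between 0.978 and 0.993. The distributions still differed slightly by group. Medians were 5.32 to 5.37 in intact and 5.39 to 5.40 in preconditioned arrays, and upper quartiles 6.97 to 7.03 and 6.94 to 6.95. The labels call the arrays biological replicates, and their number, 3 per group, limits the precision of every value below. The Y-linked genes Kdm5d (7.08 ± 0.08 and 6.93 ± 0.14), Uty (7.64 ± 0.13 and 7.45 ± 0.11) and Eif2s3y (8.18 ± 0.31 and 8.26 ± 0.09) were well expressed in intact and preconditioned lungs. Xist, the RNA of the inactive X chromosome, was low in both (3.75 ± 0.05 and 3.79 ± 0.19; SD, n = 3).

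The comparison of preconditioned with intact lungs asks which transcripts differ 1 week after low-pressure ventilation. Preconditioned lungs had less mRNA of the inducible heat shock protein gene Hspa1b, of the macrophage chemokine gene Ccl3 and of 11 other genes, among them Chordc1, Xbp1, Ctns and Hyal2. They had more of several small noncoding RNAs, among them the small nucleolar RNA Snord118. Of 22180 genes, 21 passed an adjusted p of 0.05 in limma, 13 lower and 8 higher, and in all 21 every value of one group lay beyond every value of the other. At an unadjusted p under 0.05 there were 4239 genes (19.1%, against 1109 expected by chance), 2569 lower and 1670 higher. After a further quantile normalization the split was 1830 lower and 1850 higher. The values of the groups did not overlap for 5482 genes, 24.7% against the 10% that chance gives on average for 3 against 3. Single splits can lie far from such averages, since genes vary together. Other splits of the arrays gave 230 to 1985 genes at an unadjusted p under 0.05. The first principal component held 46.6% of the variance and parted the groups, with intact replicate 1 at -0.51, intact replicates 2 and 3 at -26.5 and -28.4, and the preconditioned replicates at 12.3, 25.8 and 17.3. The count of 21 rested on few arrays: it was 1228 without intact replicate 1, 2 without intact replicate 2, 3 without intact replicate 3, and 4, 3 and 2 without preconditioned replicates 1, 2 and 3. The unadjusted count was 2693 without intact replicate 2 and 2598 without intact replicate 3.

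Hspa1b (probe set 17344126) showed the largest fall among the called genes, from 8.92 ± 0.15 to 6.37 ± 0.17 (SD, n = 3), a log2 difference of -2.55 (SE 0.12, 5.88-fold lower, adjusted p = 0.000557). Its near-identical paralog Hspa1a was at -1.16 (adjusted p = 0.0803), and signal shared between the 2 copies cannot be excluded. Ccl3 (probe set 17266967), which encodes a chemokine made by macrophages, fell from 6.48 ± 0.26 to 5.32 ± 0.10, a log2 difference of -1.16 (SE 0.14, 2.24-fold lower, adjusted p = 0.0399). Genes of protein folding in this group were Chordc1, a partner of the heat shock protein 90 chaperone (-0.88), and Xbp1, a transcription factor of the unfolded protein response (-0.65). Ctns, the lysosomal cystine transporter, fell by 0.90 and Hyal2, a hyaluronidase, by 0.82 on the log2 scale. The others were Igkj1, a joining segment of the immunoglobulin kappa locus (-1.91), Calcb, a calcitonin gene-related peptide (-1.85), the long noncoding RNA Dubr (-1.18), Ehd3 of endocytic recycling (-1.04), Uba6, a ubiquitin-activating enzyme (-0.92), Sh3bgrl3 (-0.89) and Plbd1 (-0.82). Adjusted p for these 11 genes lay between 0.0399 and 0.0430. The Ccl3 call held in 9 of the 14 settings that measured it (adjusted p from 0.0169 to 0.208, log2 difference from -1.31 to -1.07). It was lost without intact replicate 2 (0.204) and without preconditioned replicate 1 (0.0741), 2 (0.113) or 3 (0.208).

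**Figure D1:**
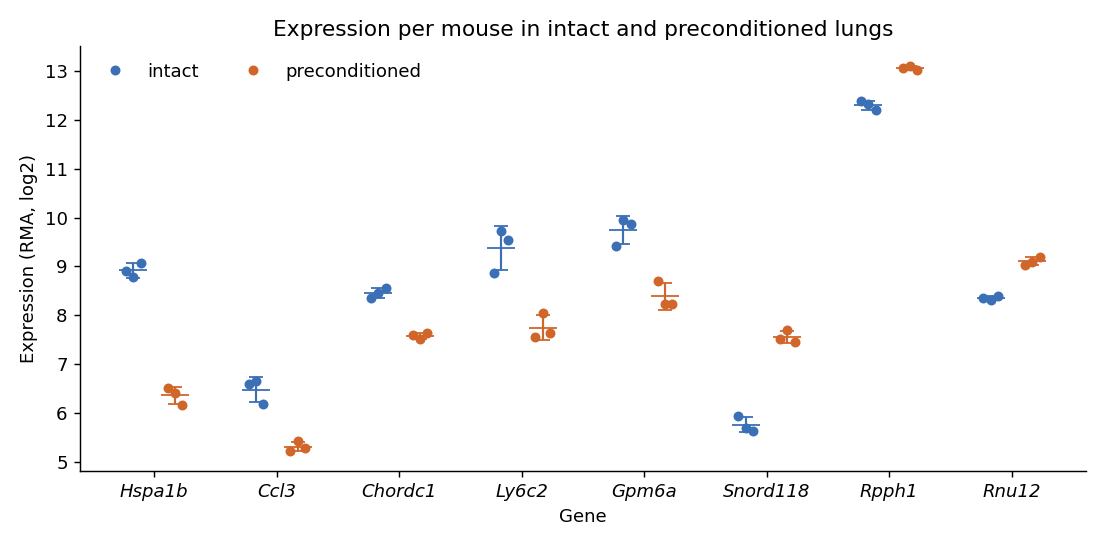
Expression (RMA, log2) of 8 genes in each intact (blue) and preconditioned (orange) lung, with points for single mice and bars for mean ± SD (n = 3). In each of these genes the values of the groups do not overlap; Ly6c2 and Gpm6a did not pass the adjusted threshold.

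Of the 8 genes that rose, 6 make small noncoding RNAs of known classes. Snord118, a small nucleolar RNA used in ribosomal RNA processing, rose from 5.77 ± 0.16 to 7.56 ± 0.13 (log2 difference 1.79, SE 0.12, adjusted p = 0.00289, n = 3). Snora41 rose by 1.51 and Snord65 by 0.86. Rpph1, the RNA of ribonuclease P, rose by 0.76, its relative Rprl2 by 0.70 and Rnu12, an RNA of the minor spliceosome, by 0.75. AF357399 was at 1.84 and is named although its group means lie under the median level of all genes (5.94), which was decided after its value was seen. The protein-coding gene was ND6, a mitochondrially encoded subunit of respiratory complex I (0.92, SE 0.10). Genes next in order of p did not pass the threshold: Cd209a was at 0.73, Rnu3a at 1.88, Scarna8 at 1.33, Scarna10 at 0.92, Rgs8 at 0.53 and Nop56 at 2.27 (adjusted p from 0.0554 to 0.0610). Other probe sets of Nop56 gave -0.09 and 0.73, and another of Cd209a gave -0.96, so that the direction for these genes depends on the probe set.

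Of 46 gene lists fixed before the data were examined, 44 had at least 5 measured genes. The X inactivation and Y chromosome lists had fewer. In limma's camera with its preset correlation of 0.01, 22 lists passed an adjusted p of 0.05, 20 lower and 2 higher in preconditioned lungs. With a correlation estimated for each list camera called 0 lists (lowest adjusted p = 0.378, and 4 lists at an unadjusted p under 0.05). The fry test, which asks whether the members of a list move one way, called 1 list, heat shock and protein folding (15 lists at an unadjusted p under 0.05), and 21 lists for change in either direction. Another split of the same 6 arrays into 3 and 3 gave 25 lists at the preset correlation. Some genes belong to several lists.

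Small nucleolar RNAs as a group were higher in preconditioned lungs. The median log2 difference over 73 measured members was 0.49 and 60 members were higher (camera adjusted p = 5.16e-18, adjusted p = 0.426 with an estimated correlation). Of these, 3 passed over all genes and 40 were higher when adjusted over the list alone. Snora73b, the next member after the called ones, was at 1.42. The mean deviation of the list from its average over the arrays was -0.20, -0.24 and -0.34 in the intact replicates and 0.12, 0.28 and 0.39 in the preconditioned ones.

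Of the lists of stress and signalling responses, 4 were lower in preconditioned lungs, while oxidative stress and NRF2 targets did not pass (median -0.11, 7 of 20 members higher, camera adjusted p = 0.0689). Handling of the animals and tissue, named above among the sources of unwanted variation, was not tested for these lists or for Hspa1b. In the heat shock and protein folding list, 20 of 21 measured members were lower (median -0.42, camera adjusted p = 2.51e-10, adjusted p = 0.378 with an estimated correlation, fry adjusted p = 0.0150). Hspa1b passed over all genes and 11 members when adjusted over the list alone, among them the constitutive chaperone Hspa8 (-0.59), the endoplasmic reticulum chaperone Hspa5 (-0.71) and its cofactor Dnajb9 (-0.61). The glucocorticoid response list had a median of -0.46 over 17 members (camera adjusted p = 1.35e-05, adjusted p = 0.426 with an estimated correlation). No member passed over all genes and 3 did over the list alone, with Cdkn1a, a cell cycle inhibitor, at -1.39, Map3k6 at -0.86, Klf9 at -0.57 and Sgk1 at -0.36. In the immediate early list the median was -0.21 over 25 members (camera adjusted p = 7.00e-05, adjusted p = 0.470 with an estimated correlation). None passed over all genes and 7 did over the list alone, with Btg2 at -0.88, Egr1 at -0.83, Fos at -1.06 and the phosphatase gene Dusp1 at -0.80. The list of NF-kB feedback and tolerance regulators, which shares Dusp1, had a median of -0.17 over 18 members (camera adjusted p = 0.00372, adjusted p = 0.511 with an estimated correlation). It had 0 members past the threshold over all genes and 5 over the list alone, with Irak3 at -0.68, Zfp36 at -0.49 and Trim30a at -0.61. Its call was lost among genes above the median level (adjusted p = 0.158), where its median stayed at -0.17. The median was -0.08 after quantile normalization again, -0.09 after cyclic loess and -0.10 without preconditioned replicate 2. The median of the immediate early list was -0.11 after quantile normalization again and -0.13 after cyclic loess.

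Of the lists of myeloid cells, those of monocytes and interstitial macrophages, alveolar macrophages and neutrophils were lower in preconditioned lungs, with no member past the threshold over all genes. The lists of dendritic cells (median -0.18, camera adjusted p = 0.0562) and of mast cells and basophils (-0.02, 0.643) did not pass. The monocyte and interstitial macrophage list had a median of -0.46 over 22 members (camera adjusted p = 2.78e-07, adjusted p = 0.448 with an estimated correlation), and 10 members were lower over the list alone. Ly6c2, a surface marker of inflammatory monocytes, was at -1.63 (9.38 to 7.75), the integrin gene Itgam at -0.96, Lyve1 at -1.45 and the chemokine receptor gene Ccr2 at -0.57. Alveolar macrophage markers had a median of -0.42 over 19 members, all 19 of them lower (camera adjusted p = 2.93e-06, adjusted p = 0.470 with an estimated correlation). Over the list alone 6 were lower, among them Olr1 (-0.81), Krt79 (-0.73) and the lysosomal marker Cd68 (-1.24), and Chil3 was at -1.25. Neutrophil markers had a median of -0.69 over 22 members (camera adjusted p = 7.03e-05, adjusted p = 0.533 with an estimated correlation) and none passed over the list alone. Their mean deviation was 0.96 in intact replicate 3 but -0.16 and 0.11 in the other intact mice, and Csf3r, the receptor of granulocyte colony-stimulating factor, was at -1.47, Slfn4 at -0.68, Clec4e at -0.89 and S100a9 at -1.18. Without intact replicate 3 the median was -0.40 for neutrophils and -0.26 for alveolar macrophages, both still called.

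Of the other blood cell lists, that of B and plasma cells did not pass (median 0.02, 10 higher and 7 lower, camera adjusted p = 0.914), and those of T and NK cells and red blood cells lost their calls in some settings. T and NK cell markers had a median of -0.22 over 23 members (camera adjusted p = 0.00466, adjusted p = 0.634 with an estimated correlation), with 0 members past either over all genes or adjusted over the list alone. Gzma was at -1.32, Ncr1 at -0.82, Prf1 at -0.78 and Cd3g at -0.85. That call was lost without intact replicate 2 (adjusted p = 0.152), without preconditioned replicate 2 (0.104) and among genes above the median level (0.259), with medians of -0.18, -0.14 and -0.40. Red blood cell genes had a median of -0.57 over 7 members (camera adjusted p = 0.0111, adjusted p = 0.479 with an estimated correlation), 0 past over all genes and 4 lower over the list alone, with Slc4a1 at -0.67, Bpgm at -0.57, Slc25a37 at -0.69 and Fech at -0.73. The red blood cell call was lost without intact replicate 1 (median -0.66, adjusted p = 0.0572) and without preconditioned replicate 3 (median -0.55, adjusted p = 0.0531). Interferon response genes had a median of -0.17 over 26 members (camera adjusted p = 0.0121, adjusted p = 0.608 with an estimated correlation), 0 past over all genes and 2 lower over the list alone, with Rsad2 at -0.69, Ifih1 at -0.49, Oasl2 at -0.72 and Ifit1 at -0.82. The interferon call was lost without intact replicate 1 (0.0572), without preconditioned replicates 2 (0.0955) and 3 (0.149) and among genes above the median level (0.1502). Its median was -0.11 without intact replicate 1 or preconditioned replicate 3, -0.38 without preconditioned replicate 1, -0.27 among genes above the median level, -0.09 after quantile normalization again and -0.10 after cyclic loess. The mean deviations of both lists overlapped between the groups, with T and NK cells at 0.03 in preconditioned replicate 3 and -0.03 in intact replicate 1, and interferon genes at 0.19 in preconditioned replicate 1, above all intact mice. Of the 28 inflammatory cytokines and chemokines, Ccl3 passed over all genes, and 6 were lower and 2 higher over the list alone. Il1b was at -1.60, Ccl9 at -0.73 and Ccl20 at 0.44. This list was not called (median -0.05, mean -0.23, camera adjusted p = 0.135, adjusted p = 0.470 with an estimated correlation), but passed after quantile normalization again (median -0.13, adjusted p = 0.0101) and after cyclic loess (-0.13, 0.0124). Its median was -0.90 among genes above the median level, where it did not pass (adjusted p = 0.0644), and lay between -0.13 and -0.02 in the other settings.

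Mesothelial, endothelial, lymphatic and coagulation lists were lower in preconditioned lungs, while smooth muscle and pericyte genes did not pass (median 0.03, camera adjusted p = 0.692), with 0 members past the threshold over all genes in each list. Mesothelial cell markers, which mark the pleural lining, had a median of -1.02 over 10 members, all lower, and 9 passed over the list alone (camera adjusted p = 1.42e-07, adjusted p = 0.448 with an estimated correlation). Gpm6a was at -1.35, Upk3b at -1.56, Bnc1 at -0.72 and the transcription factor gene Wt1 at -0.45. Endothelial cell markers had a median of -0.28 over 26 members (camera adjusted p = 0.000105, adjusted p = 0.538 with an estimated correlation), with the TGF-beta coreceptor gene Eng at -0.80, Sox18 at -0.70, Ramp2 at -0.49 and Tmem100 at -0.50. Over the list alone 7 were lower and 1 was higher. The endothelial mean deviations overlapped between the groups (0.06, 0.28 and 0.10 in intact and 0.06, -0.41 and -0.09 in preconditioned replicates). Their median was -0.13 after quantile normalization again and after cyclic loess, -0.43 without preconditioned replicate 1 and -0.15 without preconditioned replicate 2. The lymphatic endothelial list had a median of -0.31 over 8 members (camera adjusted p = 0.00130, adjusted p = 0.448 with an estimated correlation), with Lyve1 at -1.45, Mmrn1 at -1.07, Gng11 at -0.32 and Reln at -0.33, and 3 were lower over the list alone. Coagulation and fibrinolysis genes had a median of -0.21 over 16 members (camera adjusted p = 0.00173, adjusted p = 0.426 with an estimated correlation). There 6 were lower and 1 higher over the list alone, with coagulation factor gene F5 at -1.02, S100a10 at -0.42, the plasminogen activator gene Plat at -0.72 and Thbd at -0.41. The lymphatic call was lost among genes above the median level (adjusted p = 0.0756).

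Alveolar epithelial and lipid genes were also lower, again with 0 members past the threshold over all genes. Alveolar type 2 and surfactant genes had a median of -0.35 over 22 members (camera adjusted p = 0.000174, adjusted p = 0.533 with an estimated correlation), with the chemokine gene Cxcl15 at -0.63, the surfactant protein gene Sftpb at -0.49, Lamp3 at -0.91 and Scd1 at -0.67, and 3 were lower over the list alone. Ion and water transport genes had a median of -0.33 over 12 members and 5 were lower over the list alone (camera adjusted p = 0.00104, adjusted p = 0.448 with an estimated correlation). They were led by the epithelial sodium channel subunits Scnn1b (-0.79) and Scnn1g (-0.97), the water channel gene Aqp1 (-0.84) and Nedd4l (-0.39). Fatty acid and cholesterol synthesis genes had a median of -0.38 over 21 members, 20 of them lower (camera adjusted p = 7.58e-06, adjusted p = 0.511 with an estimated correlation), with Sc5d at -0.80, Elovl6 at -0.50, Elovl5 at -0.40 and Nsdhl at -0.89, and 5 were lower over the list alone. Alveolar type 1 markers had a median of -0.27 over 20 members (camera adjusted p = 0.00206, adjusted p = 0.610 with an estimated correlation), with Scnn1g, Clic3 (-0.54), Cav1 (-0.49) and Gprc5a (-0.92), and 1 was lower over the list alone. Targets of the YAP and mechanical stretch pathways had a median of -0.20 over 18 members (camera adjusted p = 0.0135, adjusted p = 0.533 with an estimated correlation), with Gadd45b at -0.70, Tgfb2 at -0.30, Ptpn14 at -0.23 and Trpv4 at -0.23, and 1 was lower over the list alone. Matrix protease and nuclear lamina genes had a median of -0.14 over 19 members (camera adjusted p = 0.00382, adjusted p = 0.479 with an estimated correlation), with Emd at -0.49, Timp3 at -0.74, Timp1 at -0.60 and Mmp19 at -0.51, and 5 were lower over the list alone. The calls for type 1 markers, YAP targets and matrix proteases were lost after quantile normalization again (adjusted p = 0.132, 0.490 and 0.0713), after cyclic loess (0.227, 0.523 and 0.0851) and among genes above the median level (0.1502, 0.328 and 0.227). Type 2 markers lost theirs after cyclic loess (0.0610), transport genes among genes above the median level (0.0539), type 1 markers without preconditioned replicate 2 (0.1004) and YAP targets without intact replicate 2 (0.0507) or preconditioned replicate 2 (0.0621). Among genes above the median level, medians were unchanged for type 1 markers (-0.27), YAP targets (-0.20), matrix proteases (-0.14) and transport genes (-0.33).

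The sizes of these alveolar shifts were not stable, and in 4 of these lists preconditioned replicate 1 lay above intact replicate 1. Mean deviations in intact and then preconditioned replicates 1, 2 and 3 were -0.16, 0.36, 0.41, 0.00, -0.29 and -0.32 for type 2 genes, and -0.07, 0.26, 0.24, 0.04, -0.41 and -0.05 for type 1 markers. The YAP and matrix protease lists overlapped between the groups as well. For fatty acid and cholesterol synthesis, intact replicate 1 (-0.157) lay just above the preconditioned replicates (-0.167, -0.162 and -0.250), with intact replicates 2 and 3 at 0.29 and 0.45. After quantile normalization again the medians were -0.09 for type 1 markers, -0.07 for YAP targets, -0.09 for matrix proteases and -0.19 for transport genes, and after cyclic loess -0.08 for type 1, -0.19 for type 2, -0.07 for YAP targets and -0.19 for transport genes. Without intact replicate 1 the type 1 median was -0.40, and without intact replicate 2 the YAP median was -0.13. Without intact replicate 3 medians were -0.12 for YAP targets, -0.21 for transport genes and -0.23 for fatty acid and cholesterol synthesis. Without preconditioned replicate 1 matrix proteases were at -0.30, and without preconditioned replicate 2 they were at -0.09, type 1 markers at -0.16 and YAP targets at -0.13.

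**Figure D2:**
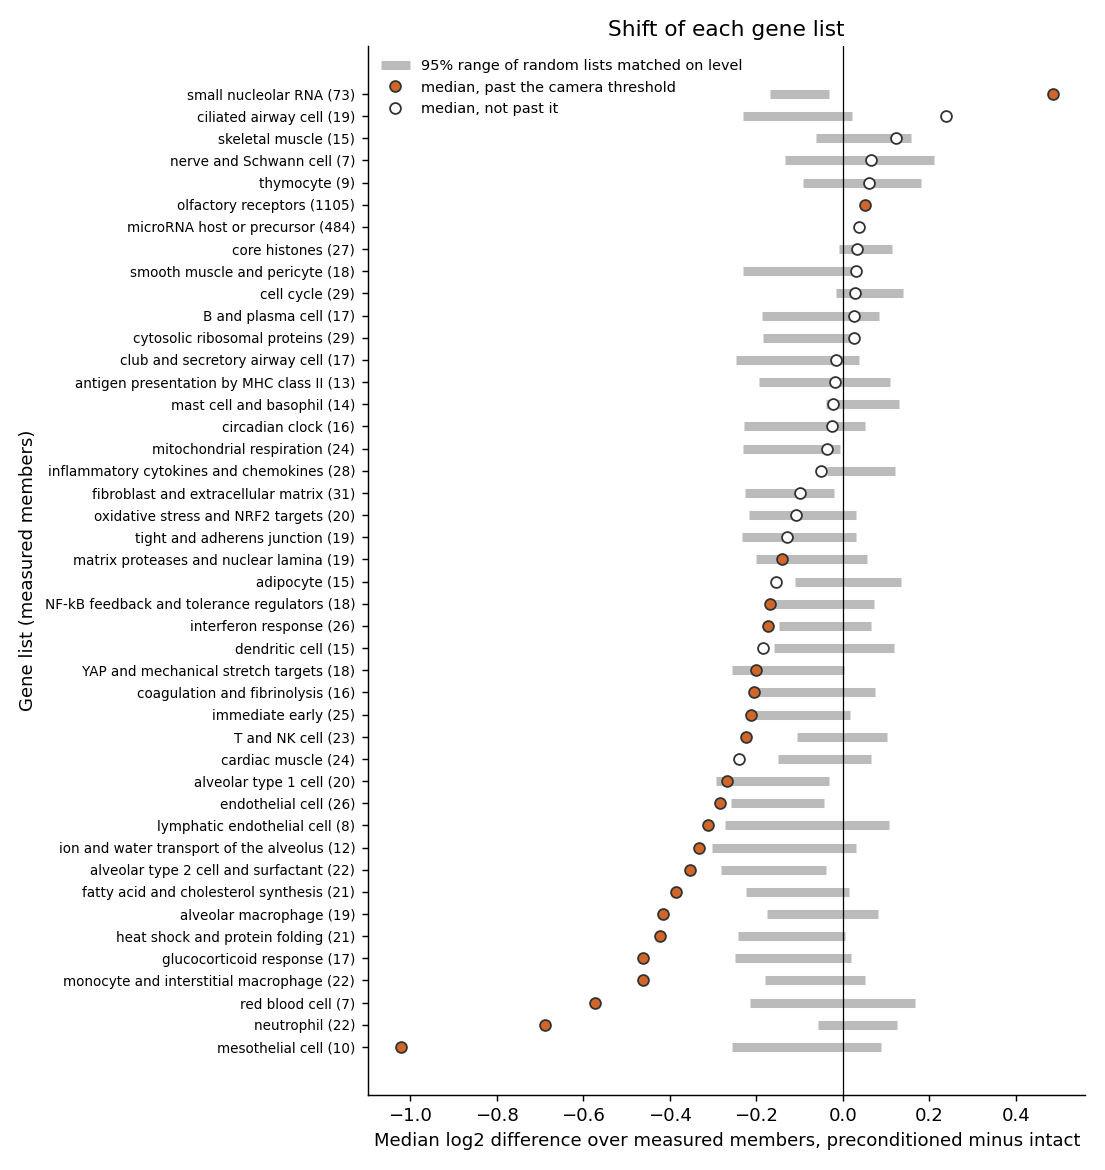
Median log2 difference (preconditioned minus intact) of each of 44 gene lists, with measured members in parentheses, filled points for lists past the camera threshold at a preset correlation of 0.01 and open points for the others. Grey bars span the central 95% of 10000 random lists matched on mean level, drawn for lists of up to 300 genes; the mesothelial list lies lowest (-1.02) and small nucleolar RNAs highest (0.49), and the higher median of olfactory receptors (0.05) was not kept after quantile normalization again.

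Lists of other cell types and processes did not pass the camera threshold. Airway and heart muscle markers varied strongly among mice of a group: the club and secretory cell list deviated by -0.998, 1.34 and -0.07 and the cardiac muscle list by -1.11, 0.86 and -0.22 in preconditioned replicates 1, 2 and 3. Without preconditioned replicate 2, cardiac muscle (median -0.63), club and secretory cells (-0.42), adipocytes (-0.30), NRF2 targets (-0.17), tight junctions (-0.14), mitochondrial respiration (-0.13) and microRNA precursors (0.05) passed, and without preconditioned replicate 1 ciliated cells (0.47) and fibroblast and matrix genes (-0.32) did. Without intact replicate 2, dendritic cells (-0.23), adipocytes (-0.25) and NRF2 targets (-0.09) passed, without intact replicate 3 dendritic cells (-0.26) and ciliated cells (0.31), and without intact replicate 1 tight junctions (-0.21) and microRNA precursors (0.06). Ribosomal proteins (0.16 in both) and ciliated cells (0.32 and 0.31) passed after quantile normalization again (adjusted p = 0.0173 for both) and after cyclic loess (0.0115 and 0.0134). Among genes above the median level ciliated cells (0.22, adjusted p = 0.00899) and microRNA precursors (0.19, adjusted p = 2.25e-06) passed. With array weights NRF2 targets (-0.11), tight junctions (-0.18) and microRNA precursors (0.05) passed, and with the mean over probe sets dendritic cells (-0.18) did. With all mice, medians were -0.24 for cardiac muscle, -0.02 for club and secretory cells (mean 0.18), -0.16 for adipocytes, -0.11 for NRF2 targets, -0.13 for tight junctions, -0.04 for mitochondrial respiration, 0.04 for microRNA precursors, 0.24 for ciliated cells, -0.10 for fibroblast and matrix genes and -0.18 for dendritic cells. The median was 0.12 for skeletal muscle, -0.02 for mast cells and basophils, -0.02 for antigen presentation by MHC class II, 0.06 for thymocytes, 0.02 for cytosolic ribosomal proteins, -0.02 for the circadian clock, 0.03 for cell cycle genes and 0.02 for B and plasma cells (mean -0.03). Median and mean also differed in sign for smooth muscle and pericytes (0.03 and -0.07), core histones (0.03 and -0.04) and nerve and Schwann cells (0.07 and -0.01).

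Fold differences depended on the level of a gene. The median log2 difference was 0.05 in the lowest of 10 equal groups of genes by mean level, 0.10 in the fourth and -0.16 in the highest, against 0.01 over all genes. Among the lists called lower, 4 had medians within the central 95% of random lists matched on level: alveolar type 1 (percentile 4.91), NF-kB feedback (3.25), YAP targets (10.96) and matrix proteases (14.69). Olfactory receptor genes, which lung is not known to use widely and which lie at low levels on the array, had a median of 0.05 over 1105 members (camera adjusted p = 0.00206, adjusted p = 0.470 with an estimated correlation). None passed over all genes or over the list alone. The median was 0.15 among genes above the median level, and the list's call was lost after quantile normalization again (median 0.0031, adjusted p = 0.921, with the direction of the test reversed) and after cyclic loess (-0.0055, adjusted p = 0.975).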

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

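Cyclic loess was the alternative chosen after the data were seen. The 21 called genes became 76 among genes above the median level, 33 after median centring, 55 with an intensity trend and robust prior, 1125 with array weights, 642 at an adjusted p under 0.1, and 2 to 1228 when an array was left out. Quantile normalization again (20), the mean of a gene's probe sets (30) and cyclic loess (28) gave counts within 1.5 times. Among all 41345 probe sets 12 passed, of which 2 were among the 21 and 9 are not in the annotation. The 4239 genes at an unadjusted p under 0.05 became 2712 among genes above the median level, 7297 among all probe sets, and 2598 to 5490 when an array was left out. Of the 21 genes, Hspa1b and Snord118 were called under all 15 settings that refit single genes. The 22 lists became 0 with an estimated correlation and 1 with fry, and were 15 to 25 elsewhere. The olfactory receptor list turned direction after quantile normalization again (median 0.0031). Intact replicate 1 had the lowest array weight (0.557), and leaving it out gave the 1228. Beyond fewer genes or arrays tested, the cause of these shifts was not tested.

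With the replicate number as a block, 4 genes passed, all among the 21 but not Ccl3 (adjusted p = 0.180), and 23 lists, the 22 and dendritic cells (adjusted p = 0.0362). The deviations of equal-numbered arrays correlated at -0.06, -0.31 and -0.06, so arrays of equal number were not alike in expression. Whether the numbers mark a shared day or batch cannot be read from these values. Signal over background is not analysed here, so low-level genes are limited by unknown noise.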

Other observations

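The mitochondrially encoded ND6, transcribed from the opposite strand to the other mitochondrial mRNAs, was higher by 0.92, while the 9 others measured (ND1, ND2, ND3, ND4, ND4L, ND5, COX1, COX3 and CYTB, a set chosen after the values were seen) differed by between -0.04 and 0.09 and none passed the threshold. Those 9 had group means from 12.81 to 13.64, close to the highest values of the arrays, where saturation can hide a change, so whether they moved with ND6 is not readable here. Genes of the circadian clock went in opposite directions without passing the threshold over all genes. Dbp, an output gene of the clock, was at 1.00, Per3 at 0.61 and Cry2 at 0.41, while the activators Arntl, Npas2 and Clock were at -0.83, -0.78 and -0.47. Over the clock list alone, 3 genes were higher and 3 lower.

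The tests of other small RNAs, of blood, of the alveolar type 1 list alone and of the sampling hour were chosen after the results were seen. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 21 genes, as 1 of 10 did, against at most 0 in the others, and 4239 genes at an unadjusted p under 0.05, again 1 of 10, against at most 1985. For lists, 2 of the 10 splits gave at least the real 22, the other being intact replicate 1 with preconditioned replicates 2 and 3 (25 lists).

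Small nucleolar RNAs were higher in preconditioned lungs. A trend of the fold difference with level is argued against, since the list's median lay at percentile 100 of random lists matched on level. Other small noncoding RNAs were higher too, with a median of 0.50 (0.503, 95% interval over genes from 0.304 to 0.752) and 15 of 16 higher. The set holds Rnu12, Rpph1, Rprl2, Rnu3a, Scarna8 and Scarna10, already named above as higher, and Rnu3a is itself a small nucleolar RNA. A larger yield of small RNA in the preconditioned samples may account for the pattern. Some other values were closer to no change, but they do not settle whether every kind rose. MicroRNA hosts and precursors had a median of 0.04 over 484 members (282 higher and 202 lower). Among genes above the median level their median was 0.19 and the list passed (camera adjusted p = 2.25e-06). Rny1 was at 0.14 and Scarna2 at -0.19. Rn7sk was at 0.09, with group means of 13.72 and 13.82, close to the highest values of the arrays, where saturation can hide a change. The labels give no extraction batch, and a change in the lungs themselves stays open as well.

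Lists of 10 cell types were lower. A trend with level alone is argued against for most of them, since 90% (9 of 10) had medians under percentile 2.5 of level-matched lists, but the alveolar type 1 list at percentile 4.91 may follow that trend, and the type 2 list moved from a median of -0.35 to -0.19 under cyclic loess and lost its call. The 10 lists were picked because they were called lower, and matched lists draw unrelated genes. The percentiles therefore concern the level of the genes and say nothing on chance. Less blood would raise the markers of every resident cell type, and over the 188 genes of 10 resident lists the mean difference was -0.23 (-0.2257, from 0.11 ± 0.12 to -0.11 ± 0.08, n = 3), but the groups overlapped when the endothelial or the type 2 list was left out. Of these lists the mesothelial (-0.96), alveolar macrophage (-0.49) and lymphatic endothelial (-0.48) ones were lower on average with the arrays apart, while ciliated (0.19) and club and secretory cells (0.18) were higher on average and overlapped. The B cell list had a median of 0.0249 (95% interval over members from -0.123 to 0.0676). It does not decide between less blood and a change in the cells for the blood cell lists. The lower resident mean and the lower mesothelial, alveolar macrophage and lymphatic endothelial lists run opposite to what less blood alone predicts. That mean did not stay apart without the endothelial or the type 2 list, and these lower lists were picked by their result. Less blood was therefore not excluded for resident cells. Differences in which part of the lung was sampled and an effect of preconditioning both stay open as untested.

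Another hour of sampling for the 2 groups was weighed for the clock genes. Over the whole clock list, the mean of 12 genes grouped as outputs minus that of 4 grouped as activators was 0.70 higher in preconditioned lungs (0.6968), but the arrays overlapped (0.13, -0.44 and -0.73 in intact and 0.36, 0.10 and 0.59 in preconditioned replicates). The output group included clock repressors, such as the Per and Cry genes, and the activator group included the repressor Nfil3. The genes were put into these groups after the opposite moves were seen, and Per1 (-0.47), Bhlhe40 (-0.31) and Cry1 (-0.22) of the output group were lower. The labels used here give no hour, so it cannot be told apart from an effect of ventilation on the clock or from no shift of the clock.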
